A study of Hordeum vulgare with 18 samples.

How the data were processed

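Messenger RNA was measured by RNA sequencing in barley roots of 2 genotypes, ZDB160 and ZDB475, after 24 h in nutrient solution alone, with arsenate, or with arsenate and phosphate. The series holds 18 samples in 6 groups of 3. Values per library were used for 15 of them in 5 groups. The libraries of the ZDB160 control were not analysed here, and ZDB160 was compared with its control only through the comparison tables that the authors deposited.

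Reads were aligned and transcripts assembled with HISAT and StringTie, per the submitters' processing notes. Their versions, the genome build and the counting tool are not given in the sources used here. Per the file headers, each library's file lists genes with an expected count and an FPKM. Per the file headers, an expected count is an estimated number of reads per gene, so it can hold a fraction, and the authors deposited it without scaling. The authors also deposited FPKM, the expected count scaled by transcript length and by depth, and listed 28120 to 30139 genes per library. A gene missing from a library's file was taken as 0. The authors deposited 4 comparison tables, of each treatment against the control of its genotype. Each holds a normalized signal per group from DESeq2, a log2 fold change and a p-value with its adjusted value, per the file headers. In these tables no group signal is 0, so the authors' log2 fold changes stay finite for genes without reads in a group. The authors' calls of higher or lower match an adjusted p under 0.05 with a log2 fold change of at least 1 in size, while the counts given here use the adjusted p alone.

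The files name 36718 genes, of which 31812 carry HORVU identifiers and 4906 carry names given by the sequencing centre. Descriptions came from the files. A protein description was used for 29.8% of genes and a KEGG name for 33.4%, and 36.8% had none. The available reference annotation uses other identifiers, so no positions are given. Genes with identical counts in every library, 276 of 27098 tested (1.02%), cannot be told apart, and near-identical copies may share reads.

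Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group, which left 27098. Libraries were scaled by the trimmed mean of M-values (TMM). The quasi-likelihood test was run on 1 coefficient per group over all 15 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 7 comparisons were each treatment against the control in ZDB475, arsenate with phosphate against arsenate in each genotype, ZDB160 against ZDB475 under each treatment, and the difference of the phosphate effect between genotypes. Standard errors (SE) were computed from the fold change and the test's F. Levels are CPM, counts on TMM-scaled library sizes brought to a common depth, given as mean ± SD of 3 libraries. Where every library of a group held 0 reads, the fold was computed against 3 counts over the group and is a lower bound. Where a group held 1 to 3 reads, only the levels are given. Such bounds cover counting error only.

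Gene lists were defined by patterns on descriptions, and 97 accidental matches were taken out. A list was tested where at least 5 members were tested, which held for 29 of the 30 lists. Each was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over lists, and repeated with a correlation estimated from the residuals and with fry. The authors' tables were tested with cameraPR on their signed statistics, with the same preset correlation and no repeat with an estimated one or with fry. The 30 lists were phosphate transport and starvation response; aquaporins; arsenate reduction; glutathione, phytochelatin and metallothionein; glutathione S-transferases; sulfate uptake and assimilation; ABC transporters; class III peroxidases; antioxidant enzymes; heat shock proteins and chaperones; WRKY, MYB and NAC factors; ethylene; jasmonate; auxin; abscisic acid, LEA and dehydrins; iron and zinc uptake; nitrate and ammonium; expansins and cell wall remodelling; phenylpropanoid and lignin; cytochrome P450; UDP-glycosyltransferases; pathogenesis-related proteins and chitinases; glycolysis and fermentation; ribosomal proteins; histones and DNA replication; and, as markers of tissues, photosynthesis, seed storage and Casparian strip membrane proteins.

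Genes named here were chosen by rule. Per comparison of the libraries these were the 10 largest changes in each direction among genes past the threshold whose replicates did not overlap, with a mean of at least 1 CPM in a group and a description, at most 2 per description. Up to 4 list members per direction with the smallest adjusted p were added. For the authors' tables the overlap was not used, and the minimum of 1 applied to signals scaled by length and depth. The tests, lists, naming rule (with its minimum in FPKM throughout) and most alternatives were fixed before the data were examined. The alternatives were other scaling (RLE), no filter on low counts, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) with the authors' FPKM, a replicate block, a minimum fold change, only the groups compared, and each library left out in turn. Chosen after the data were seen were total counts as the only scaling, limma voom with a quality weight per library, leaving out a pair of libraries that stand apart, and a test of whether the response differed between genotypes. That test divided the difference of the authors' log2 fold changes by the combined standard error recovered from their DESeq2 p-values, with Benjamini-Hochberg adjustment. It treats the 2 tables as independent and is approximate.

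The comparisons were tested on simulated counts with 200 genes changed by known folds. For arsenate against control in ZDB475, 4% of genes changed 2-fold were recovered, 48% at 4-fold, 78% at 8-fold and 78% at 16-fold, with 7 false calls among 26642 genes. For arsenate with phosphate against arsenate, these shares were 2%, 46%, 76% and 92% in ZDB475 with 5 false calls, and 6%, 52%, 68% and 96% in ZDB160 with 6 false calls. With 200 genes changed the adjusted threshold is stricter than where many genes pass, so for such comparisons these shares do not give the power. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.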

Results

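Roots of 2 barley genotypes were sampled after 24 h of treatment. The labels describe ZDB160 as cultivated and arsenic-tolerant and ZDB475 as wild and arsenic-sensitive. Plants in hydroponic culture received nutrient solution alone (control), 100 µM arsenate, or 100 µM arsenate with 50 µM phosphate. Arsenate is a chemical analogue of phosphate that roots take up through phosphate transporters. Each of the 3 replicates per group was a pool of the roots of 10 seedlings, so the p-values measure the spread between these pools. Total expected counts in the ZDB160 libraries were 23478198, 23567193 and 23486061 for arsenate replicates 1 to 3, and 24536982, 22190140 and 23126888 for arsenate with phosphate. In ZDB475 they were 19773387, 21848947 and 23890273 for the control, 22309615, 22429768 and 22141178 for arsenate, and 21867713, 22553113 and 23193242 for arsenate with phosphate.

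Most replicates lay close together in their gene levels. The 3 ZDB475 controls correlated at 0.982 to 0.99 across genes, which are not independent replicates, and the libraries given arsenate with phosphate at 0.975 to 0.987 in ZDB475 and 0.987 to 0.989 in ZDB160. A pair of arsenate libraries stood apart. Replicate 1 of ZDB475 under arsenate correlated at 0.878 and 0.869 with its replicates, which reached 0.967 with each other. Its 100 most abundant genes held 29.58% of its counts, against 11.3% to 17.91% elsewhere, and its TMM factor was 0.413. Replicate 3 of ZDB160 under arsenate correlated at 0.951 and 0.953 with its replicates, which reached 0.993 with each other, and at 0.979, 0.977 and 0.964 with the ZDB160 libraries given phosphate as well. Replicate 3 of ZDB475 under arsenate also lay near the ZDB475 libraries given phosphate, at 0.98, 0.978 and 0.971, against 0.967 with replicate 2 of its group.

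**Figure D1:**
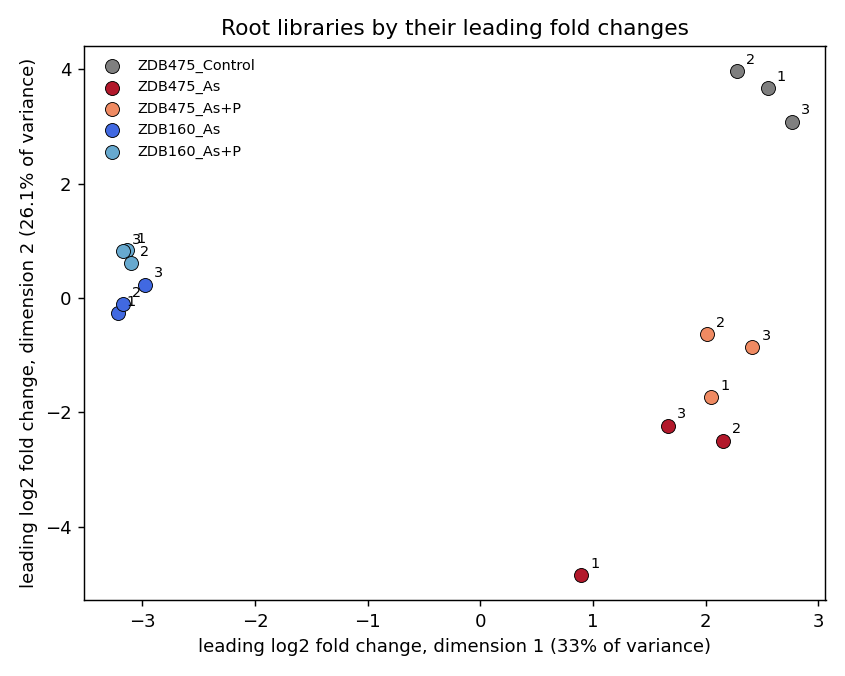
Leading log2 fold changes between the 15 root libraries, as distances on 2 axes that hold 33% and 26.1% of the variance. Points are libraries, coloured by group. Replicate 1 of ZDB475 under arsenate lies away from its group.

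The response of the sensitive genotype to arsenate was compared first. In ZDB475, a glutathione S-transferase, an enzyme that joins glutathione to reactive compounds, rose from 5.28 ± 1.14 to 227 ± 5.03 CPM (HORVU1Hr1G049070, log2 fold change 5.43 ± 0.442 SE, n = 3, adjusted p = 1.31e-05). The aquaporin HORVU5Hr1G055200, a water channel, fell from 1890 ± 612 to 82.3 ± 45.2 CPM (−4.52 ± 0.445, n = 3, adjusted p = 2.99e-05). A glycerophosphodiester phosphodiesterase, which releases phosphate from lipid remnants, rose from 31.9 ± 9.82 to 1496 ± 804 CPM (HORVU2Hr1G070700, 5.55 ± 0.557, n = 3, adjusted p = 3.31e-05), while the phosphate transporter HORVU4Hr1G083550 fell from 239 ± 180 to 3.81 ± 1.22 CPM (−5.95 ± 1.1, n = 3, adjusted p = 0.0012). L-lactate dehydrogenase, a fermentation enzyme, rose from 0.212 ± 0.0282 to 77.2 ± 33.3 CPM (HORVU2Hr1G012830, 8.47 ± 0.543, n = 3, adjusted p = 4.88e-06).

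Among the largest changes in ZDB475 under arsenate were genes without reads in one group. The protease gene nepenthesin-2 (HORVU3Hr1G022450) had 0 reads in the controls and 112 ± 65 CPM under arsenate, at least 2620-fold higher (adjusted p = 5.89e-05), and its fitted log2 fold change of 14.34 was 13.76 without arsenate replicate 3. A fasciclin-type gene described as a transforming growth factor-beta-induced protein (HORVU4Hr1G082970) had 44.9 ± 8.64 CPM in the controls and 0 reads under arsenate, at least 799-fold lower. An endoglucanase, a cell wall enzyme, fell at least 266-fold (HORVU2Hr1G120100), and a peroxidase at least 165-fold (BGI_novel_G000646). A cytochrome P450 of family 76 rose from 0.86 ± 0.233 to 309 ± 56.7 CPM (HORVU2Hr1G121170, 8.49 ± 0.458, adjusted p = 2e-06). A cinnamyl-alcohol dehydrogenase of lignin synthesis rose from 32.3 ± 4.55 to 1360 ± 688 CPM (HORVU0Hr1G012940, 5.40 ± 0.454, adjusted p = 1.34e-05). With a quality weight per library, the calls of HORVU4Hr1G082970 and HORVU2Hr1G120100 ended (limma voom adjusted p = 0.105 and 0.248).

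Genes of arsenic binding and sulfur supply moved in ZDB475 under arsenate. Of 92 glutathione S-transferases tested, 51 rose, 11 fell and 30 did not pass (52 and 13 adjusted over the list alone). The list as a whole rose, with a median log2 fold change of 2.42 (camera adjusted p = 2.43e-08, adjusted p = 0.222 with an estimated correlation). HORVU3Hr1G107170 was among those that fell (−2.01 ± 0.326, adjusted p = 0.000551). Of 38 genes of sulfate uptake and assimilation, 21 rose, 5 fell and 12 did not pass (21 and 5 adjusted over the list alone, camera adjusted p = 0.00425, adjusted p = 0.222 with an estimated correlation). A cysteine synthase rose from 2.76 ± 1.05 to 32.1 ± 6.77 CPM (HORVU6Hr1G063480, 3.54 ± 0.377), whereas another cysteine synthase (HORVU7Hr1G021860, −2.59 ± 0.283) and an adenylylsulfate kinase (HORVU4Hr1G070220, −3.32 ± 0.411) fell.

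The glutathione, phytochelatin and metallothionein list fell in ZDB475 under arsenate, with 4 of 13 members higher, 8 lower and 1 not passing (4 and 9 adjusted over the list alone, camera adjusted p = 0.0285, adjusted p = 0.482 with an estimated correlation). Without arsenate replicate 1 its adjusted p was 0.0596. Glutamate-cysteine ligase, the first enzyme of glutathione synthesis, rose from 195 ± 37.6 to 596 ± 201 CPM (HORVU1Hr1G015590, 1.61 ± 0.287, adjusted p = 0.000974). A glutathione synthase fell (HORVU7Hr1G100570, −5.41 ± 0.629, adjusted p = 7.48e-05), as did the metallothionein HORVU1Hr1G059580, a metal-binding protein, from 589.8 ± 363 to 6.95 ± 2.85 CPM, while the metallothionein HORVU3Hr1G013840 rose (2.68 ± 0.406). Phytochelatin synthase, which makes the peptides that bind arsenic, rose by a log2 fold change of 3.77 ± 0.952 (HORVU7Hr1G040110, adjusted p = 0.00761), and without arsenate replicate 1 by 0.73 (adjusted p = 0.0212). Its adjusted p was 0.0648 with a quality weight per library and 0.0811 with only the groups compared.

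Phosphate genes of ZDB475 went both ways under arsenate, with 21 of 72 higher, 9 lower and 42 not passing (21 and 10 adjusted over the list alone, camera adjusted p = 0.4). An inositol-pentakisphosphate 2-kinase, which makes a phosphate store, rose (HORVU2Hr1G091790, 2.82 ± 0.354, adjusted p = 0.000119). Aquaporins fell as a list, with 2 of 37 higher, 24 lower and 11 not passing (2 and 26 adjusted over the list alone, median −2.38, camera adjusted p = 1.05e-08, adjusted p = 0.222 with an estimated correlation). One that rose was the nodulin 26-like channel HORVU7Hr1G043590 (5.30, and 3.82 without arsenate replicate 3).

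Iron and zinc uptake genes fell in ZDB475 under arsenate, with 13 of 85 higher, 39 lower and 33 not passing (14 and 40 adjusted over the list alone, median −1.09, camera adjusted p = 0.000223, adjusted p = 0.468 with an estimated correlation). A vacuolar iron transporter fell from 304 ± 72.6 to 28.7 ± 7.1 CPM (HORVU5Hr1G060370, −3.41 ± 0.397, adjusted p = 7.52e-05), and the metal transporter ZIP8 fell as well (HORVU1Hr1G070450, −3.62 ± 0.492). IDS3, a dioxygenase that makes the iron chelator mugineic acid, went from 355 ± 441 CPM to 3 reads in all, 0.0463 ± 0.0802 CPM (HORVU4Hr1G081520, adjusted p = 0.000265), a call that ended with a quality weight per library (adjusted p = 0.445).

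Peroxidases of the cell wall fell in ZDB475 under arsenate, with 42 of 266 higher, 121 lower and 103 not passing (43 and 127 adjusted over the list alone, median −1.15, camera adjusted p = 5.85e-06, adjusted p = 0.222 with an estimated correlation). HORVU3Hr1G072260 rose among them (2.41 ± 0.281) and HORVU0Hr1G006290 fell (−6.22 ± 0.67). Expansins and cell wall remodelling genes fell too, with 38 of 242 higher, 81 lower and 123 not passing (38 and 85 adjusted over the list alone, camera adjusted p = 0.00425, adjusted p = 0.468 with an estimated correlation). The fasciclin-like gene HORVU3Hr1G061130 fell (−4.42 ± 0.489) and the expansin HORVU4Hr1G067850 rose (4.99 ± 0.642).

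Heat shock, WRKY, abscisic acid and cytochrome P450 genes rose as lists in ZDB475 under arsenate. Of 211 heat shock proteins and chaperones, 82 rose, 23 fell and 106 did not pass (83 and 25 adjusted over the list alone, camera adjusted p = 0.00278, adjusted p = 0.468 with an estimated correlation). Their median was 0.54, or 0.49 with members at 0 reads set to their bound. The co-chaperone HORVU7Hr1G033430 rose (4.09 ± 0.397) and HORVU3Hr1G081930, another DnaJ gene, fell (−2.28 ± 0.257). Of 56 WRKY transcription factors, 25 rose, 4 fell and 27 did not pass (25 and 4 adjusted over the list alone, camera adjusted p = 0.00932, adjusted p = 0.482 with an estimated correlation), WRKY2 among the risers (HORVU5Hr1G072020, 1.60 ± 0.251). Of 40 abscisic acid, LEA and dehydrin genes, which mark water stress, 22 rose, 4 fell and 14 did not pass (22 and 4 adjusted over the list alone, camera adjusted p = 0.0303, adjusted p = 0.483 with an estimated correlation). Without both libraries that stood apart, this list had an adjusted p of 0.0581. Its LEA gene HORVU1Hr1G079290 rose by 8.78 ± 0.978, by 7.46 without arsenate replicate 1 and by 9.74 without control replicate 1, while the abscisic acid receptor gene HORVU1Hr1G050110 fell from 64.6 ± 4.78 to 32.3 ± 11.1 CPM (adjusted p = 0.00554, and 0.0865 with only the groups compared). Of 88 cytochrome P450 genes, 40 rose, 18 fell and 30 did not pass (43 and 21 adjusted over the list alone, camera adjusted p = 0.0209, adjusted p = 0.483 with an estimated correlation), and without arsenate replicate 1 the adjusted p was 0.0587.

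Ribosomal protein and histone genes fell as lists in ZDB475 under arsenate. Of 317 ribosomal protein genes, 17 rose, 94 fell and 206 did not pass (10 and 7 adjusted over the list alone, median −0.82, camera adjusted p = 5.85e-06, adjusted p = 0.676 with an estimated correlation). The S9e gene fell (HORVU2Hr1G028510, −1.39 ± 0.318) and the acidic protein P2B rose (HORVU7Hr1G091910, 5.62 ± 0.545). Of 230 histone and DNA replication genes, 12 rose, 73 fell and 145 did not pass (12 and 48 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.676 with an estimated correlation), among them histone H1 (HORVU5Hr1G095340, −1.58 ± 0.369) and histone H4 (HORVU6Hr1G011540, −1.17 ± 0.279). Their median was −0.77, or −0.75 with members at 0 reads set to their bound.

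The other lists did not pass as a whole in ZDB475 under arsenate, though members did. MYB factors had 47 of 132 higher and 25 lower (51 and 25 adjusted over the list alone, camera adjusted p = 0.201), and NAC factors 15 of 34 higher and 4 lower (15 and 4 adjusted over the list alone, adjusted p = 0.134). Ethylene genes had 22 of 50 higher and 6 lower (22 and 8 adjusted over the list alone, adjusted p = 0.0648), jasmonate genes 20 of 55 and 8 (21 and 8, adjusted p = 0.134), and auxin genes 25 of 134 and 33 (26 and 33, adjusted p = 0.503). ABC transporters had 20 of 65 higher and 16 lower (21 and 16 adjusted over the list alone, adjusted p = 0.795), antioxidant enzymes 23 of 84 and 11 (25 and 12, adjusted p = 0.637), and nitrate and ammonium genes 9 of 39 and 8 (9 and 8, adjusted p = 0.795). Phenylpropanoid and lignin genes had 31 of 92 higher and 18 lower (33 and 20 adjusted over the list alone, adjusted p = 0.34), UDP-glycosyltransferases 13 of 44 and 13 (13 and 15, adjusted p = 0.865), and pathogenesis-related proteins and chitinases 41 of 134 and 34 (41 and 34, adjusted p = 0.865). Glycolysis and fermentation genes had 37 of 109 higher and 21 lower (37 and 21 adjusted over the list alone, adjusted p = 0.243). Arsenate reduction had 0 of 8 members higher or lower by edgeR (0 and 0 adjusted over the list alone, adjusted p = 0.865). The photosynthesis marker list had 9 of 33 higher and 5 lower (11 and 6 adjusted over the list alone, adjusted p = 0.865). The Casparian strip list had 1 of 5 lower (1 adjusted over the list alone, adjusted p = 0.795). That gene, Casparian strip membrane protein 1, marks the endodermis and fell from 95.4 ± 20.5 to 7.6 ± 6.02 CPM (HORVU2Hr1G089180, −3.62 ± 0.851, adjusted p = 0.00507). The seed storage list had 3 tested members, which is under the minimum for a list, and 1 of these is a phosphatase subunit matched by its description.

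Of 27098 genes tested, 6550 rose and 4717 fell in ZDB475 under arsenate, and without both libraries that stood apart 6720 and 6621. The fit with only the groups compared called 5592 in all, and limma on log2 FPKM placed 33.3% of its calls on the higher side, against 58.1%. Scaling by total counts instead of TMM moved the median log2 fold change of all genes to −0.44, and changes are relative to the TMM scale.

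**Figure D2:**
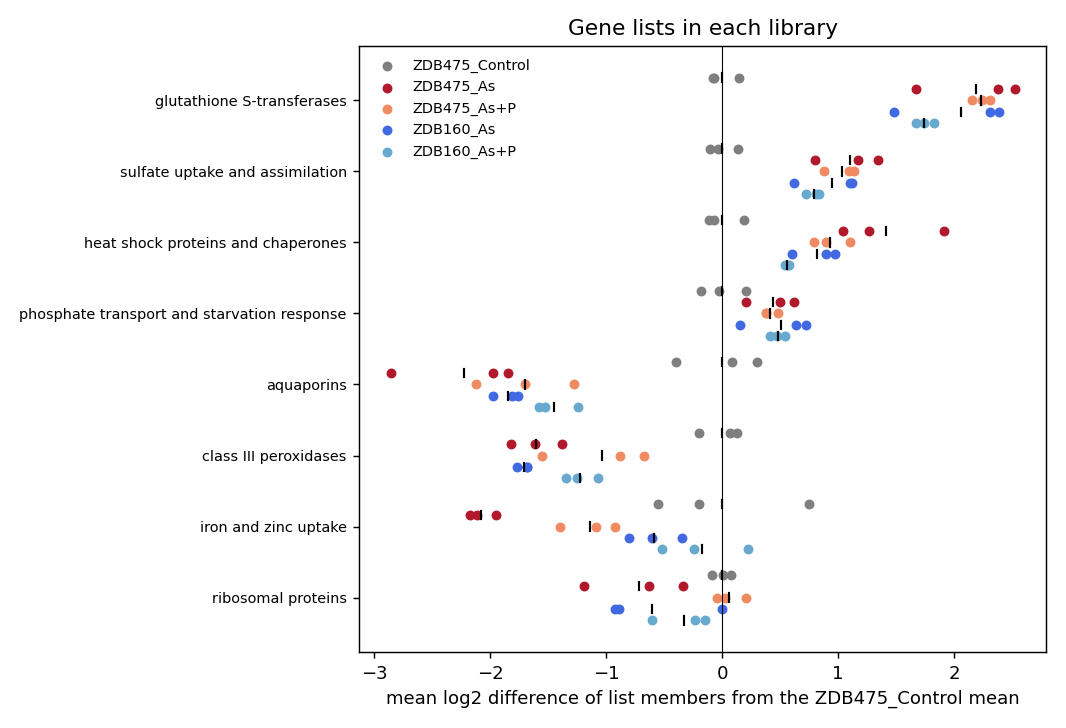
Mean log2 difference of 8 gene lists from the mean of the ZDB475 controls, per library and group. Points are libraries and bars are group means of 3. Glutathione S-transferases lie above the ZDB475 controls and aquaporins below them in both treatments and genotypes. The ZDB160 points include differences between genotypes, since no ZDB160 control is shown.

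Arsenate with phosphate was compared with the control in ZDB475, which asks what remained of the response when phosphate was added. The glutathione S-transferase HORVU1Hr1G049070 rose to 193 ± 15.2 CPM (5.19 ± 0.438 SE, n = 3, adjusted p = 3.24e-05), and another, GSTU6, rose by 6.40 ± 0.514 (HORVU1Hr1G049260, n = 3, adjusted p = 2.6e-05). The aquaporin HORVU5Hr1G055200 fell to 122 ± 26 CPM (−3.96 ± 0.433, n = 3, adjusted p = 0.000122). The glycerophosphodiester phosphodiesterase HORVU2Hr1G070700 rose to 219 ± 51.2 CPM (2.78 ± 0.49, n = 3, adjusted p = 0.00244), and the phosphate transporter HORVU4Hr1G083550 fell by 6.69 on the log2 scale (SE 1.13, n = 3, adjusted p = 0.0019). Nepenthesin-2 (HORVU3Hr1G022450) was at least 1540-fold higher than its 0 reads in the controls (65.4 ± 39.9 CPM, adjusted p = 0.000181), and its fitted log2 fold change of 13.57 was 12.94 without replicate 2 given both. The lectin horcolin, a defence protein, fell from 575 ± 452 to 0.683 ± 0.465 CPM (HORVU7Hr1G059330, −9.71 ± 1.86, adjusted p = 0.00402).

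Of 92 glutathione S-transferases, 44 rose, 3 fell and 45 did not pass in ZDB475 given both (52 and 6 adjusted over the list alone, camera adjusted p = 1.47e-18, adjusted p = 0.0904 with an estimated correlation), with a median of 2.21, or 2.12 with members at 0 reads set to their bound. HORVU3Hr1G083520 was among those that fell, from 1.8 ± 0.975 CPM to 3 reads in all (adjusted p = 0.000837). Of 37 aquaporins, 1 rose, 20 fell and 16 did not pass (3 and 23 adjusted over the list alone, camera adjusted p = 2.4e-12, adjusted p = 0.0904 with an estimated correlation), and the riser was the channel HORVU7Hr1G043590 (5.71 ± 0.838). Sulfate genes had 12 of 38 higher, 3 lower and 23 not passing (15 and 3 adjusted over the list alone, camera adjusted p = 0.00046, adjusted p = 0.0904 with an estimated correlation). The cysteine synthase HORVU6Hr1G063480 rose to 40.5 ± 13.2 CPM (3.87 ± 0.382), and the adenylylsulfate kinase HORVU4Hr1G070220 fell (−2.39 ± 0.394). Glutathione, phytochelatin and metallothionein genes had 3 of 13 higher, 7 lower and 3 not passing (3 and 8 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.318 with an estimated correlation), with glutamate-cysteine ligase higher (HORVU1Hr1G015590, 1.53 ± 0.287) and the glutathione synthase HORVU7Hr1G100570 lower (−4.87 ± 0.608).

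Peroxidases fell in ZDB475 given both, with 22 of 266 higher, 48 lower and 196 not passing (25 and 76 adjusted over the list alone, camera adjusted p = 5.25e-06, adjusted p = 0.103 with an estimated correlation). HORVU3Hr1G074960 rose among them (3.21 ± 0.51) and BGI_novel_G000644 fell (−4.38 ± 0.522). Iron and zinc genes had 2 of 85 higher, 24 lower and 59 not passing (3 and 33 adjusted over the list alone, camera adjusted p = 5.05e-05, adjusted p = 0.311 with an estimated correlation), with ZIP8 lower (HORVU1Hr1G070450, −3.04 ± 0.476). Heat shock genes had 47 of 211 higher, 11 lower and 153 not passing (51 and 13 adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.318 with an estimated correlation), with the co-chaperone HORVU5Hr1G099410 higher (5.24 ± 0.491) and HORVU3Hr1G081930 lower (−1.78 ± 0.251). WRKY factors had 10 of 56 higher and 0 lower by edgeR (11 and 0 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.516 with an estimated correlation). Ethylene genes had 17 of 50 higher, 2 lower and 31 not passing (17 and 2 adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.318 with an estimated correlation), among them the ethylene-forming enzyme ACC oxidase (HORVU7Hr1G116830, 3.15 ± 0.5).

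Expansins and cell wall genes fell in ZDB475 given both, with 13 of 242 higher, 22 lower and 207 not passing (13 and 22 adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.417 with an estimated correlation), and without both libraries that stood apart the adjusted p was 0.0839. A polygalacturonase, which breaks down pectin, rose (HORVU3Hr1G090110, 4.64 ± 0.526) and a glucanase fell (HORVU2Hr1G044450, −3.29 ± 0.371). Cytochrome P450 genes had 22 of 88 higher, 10 lower and 56 not passing (28 and 12 adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.546 with an estimated correlation), and an adjusted p of 0.064 without arsenate replicate 1 and 0.0589 without both libraries. Phosphate genes had 10 of 72 higher and 4 lower (13 and 8 adjusted over the list alone, camera adjusted p = 0.384), and ribosomal protein genes 5 of 317 higher and 1 lower (adjusted p = 0.936).

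In ZDB475 given arsenate with phosphate, 2353 genes rose and 1578 fell against the control. The count of 3931 became 12248 with a quality weight per library, 9377 with only the groups compared and 9776 without both libraries that stood apart. It was 7496 without arsenate replicate 1, 2169 and 2391 without control replicates 2 and 3, and 2342 and 2472 without replicates 1 and 3 given both.

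Arsenate and arsenate with phosphate moved many of the same genes of ZDB475, with 2231 higher and 1319 lower in both against 568.8 and 274.7 if the calls were independent, and 0 in opposite directions by edgeR. The controls are shared, which alone gave a correlation of 0.487 in 20 simulations, against 0.835 observed across genes, and a covariance of 0.23 against 3.362. Of 3550 genes called in both, 2794 (78.7%) changed less with phosphate, and the median size of their log2 fold change was 2.41 against 3.13. Without both libraries that stood apart these were 6602 of 8205 (80.5%), and 1.36 against 1.75.

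The effect of phosphate under arsenate in ZDB475 was tested directly. No single gene passed. Lists passed by camera with the preset correlation, but no list passed with an estimated correlation or by fry. Ribosomal protein genes stood higher with phosphate, by a median of 0.83 over 317 genes (camera adjusted p = 1.83e-16, adjusted p = 0.751 with an estimated correlation), and histone genes by 0.53, or 0.52 with members at 0 reads set to their bound (adjusted p = 5.31e-05, adjusted p = 0.764 with an estimated correlation). Jasmonate genes stood lower by a median of −0.95 (adjusted p = 0.000185, adjusted p = 0.751 with an estimated correlation), and adjusted over the list alone 22 of 55 fell and 0 rose. One of these was a JAZ repressor of jasmonate signalling (HORVU4Hr1G076840, −1.04 ± 0.193 SE, n = 3, adjusted p = 0.00431 over the list alone and 0.0557 over all genes).

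Abscisic acid, LEA and dehydrin genes stood lower with phosphate in ZDB475 by a median of −1.71 (camera adjusted p = 0.000428, adjusted p = 0.751 with an estimated correlation), with 16 of 40 lower and 1 higher adjusted over the list alone, including an abscisic acid receptor gene (HORVU3Hr1G031380, −1.84 ± 0.471, and −1.05 without both libraries, adjusted p = 0.0523 over the list alone). Iron and zinc genes stood higher (adjusted p = 0.0284, adjusted p = 0.751 with an estimated correlation), with 11 of 85 higher and 1 lower adjusted over the list alone. IDS3 was among the 11 (HORVU4Hr1G081520, 3 reads in all under arsenate and 11.33 ± 11.7 CPM with phosphate, adjusted p = 0.0257 over the list alone and 0.058 over all genes), and the iron store ferritin 1 was the lower one (HORVU5Hr1G047730, −3.35 ± 0.877). Without both libraries that stood apart ferritin 1 stood lower by −0.90, and both genes had an adjusted p of 0.056 over the list alone. Without ZDB160 arsenate replicate 3, which shares the estimate of the spread, the iron list had an adjusted p of 0.0585.

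Peroxidases stood higher with phosphate in ZDB475 (camera adjusted p = 0.0232, adjusted p = 0.751 with an estimated correlation), with 35 of 266 higher and 20 lower adjusted over the list alone. Expansins and cell wall genes stood higher (adjusted p = 0.0374, adjusted p = 0.751 with an estimated correlation, 0.0585 without ZDB160 arsenate replicate 3), with 11 of 242 higher and 5 lower adjusted over the list alone. Heat shock genes stood lower by a median of −0.39, or −0.36 with members at 0 reads set to their bound (adjusted p = 0.0265, adjusted p = 0.751 with an estimated correlation), with 0 of 211 higher and 3 lower adjusted over the list alone. With total counts as the only scaling, which moved the median of all genes to 0.36 here, the median of the list was 0.11. The adjusted p was 0.583 without arsenate replicate 1 and 0.648 without both libraries. Of 72 phosphate genes, 0 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.822), among them the glycerophosphodiester phosphodiesterase HORVU2Hr1G070700 (−2.77 ± 0.489, adjusted p = 0.0028 over the list alone and 0.0537 over all genes).

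With edgeR over all genes, 0 passed between arsenate with phosphate and arsenate alone in ZDB475. The smallest adjusted p was 0.0537, and 8324 had an unadjusted p under 0.05. DESeq2 called 5520, limma on log2 FPKM 90 and limma voom with quality weights 129. The count was 7428 without arsenate replicate 3, 2160 without arsenate replicate 2, 2210 without ZDB160 arsenate replicate 3, 31 without replicate 1 given both, and 2327 without both libraries that stood apart.

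The response of the tolerant genotype to arsenate comes from the authors' deposited table, without an error per gene. In the authors' deposited table a glutathione S-transferase rose from a signal of 3.145 to 1851 in ZDB160 under arsenate (HORVU3Hr1G095620, log2 fold change 9.20, adjusted p = 5.5e-40). Methionine-gamma-lyase, which releases sulfur from methionine, rose by 8.61 in the authors' deposited table (HORVU0Hr1G000340, adjusted p = 4.7e-30), and a small heat shock protein by 8.33 (HORVU3Hr1G020490, adjusted p = 1.28e-27). The aquaporin TIP1.1 of the vacuole fell from 88650 to 6865 in the authors' deposited table (HORVU4Hr1G079230, −3.69, adjusted p = 4.3e-114). A beta-fructofuranosidase, which splits sucrose, fell by 8.44 on the log2 scale in the authors' deposited table (HORVU6Hr1G004010, adjusted p = 9.6e-41), and the phosphate transporter HORVU4Hr1G083550 by 6.10 (adjusted p = 1.63e-10).

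In the authors' deposited table for ZDB160 under arsenate, 55 of 106 glutathione S-transferases rose and 9 fell (59 and 11 adjusted over the list alone, cameraPR adjusted p = 9.64e-14). The cameraPR values here and below rest on the preset correlation alone. Aquaporins had 2 of 43 higher and 24 lower in the authors' deposited table (2 and 26 adjusted over the list alone, adjusted p = 2.66e-24), the nodulin 26-like channel HORVU7Hr1G043590 again among the higher (6.54). Peroxidases had 34 of 304 higher and 132 lower (40 and 141 adjusted over the list alone, adjusted p = 6.56e-13) in the authors' deposited table, and expansins and cell wall genes 26 of 298 and 95 (27 and 101, adjusted p = 5.76e-06). Heat shock genes had 68 of 242 higher and 26 lower in the authors' deposited table (71 and 27 adjusted over the list alone, adjusted p = 0.00567), and sulfate genes 18 of 50 and 6 (20 and 6, adjusted p = 0.0193). A sulfate transporter rose by 3.92 in the authors' deposited table (HORVU4Hr1G071250) while the cysteine synthase HORVU7Hr1G021860 fell by 1.79. Iron and zinc genes had 9 of 97 higher and 22 lower in the authors' deposited table (9 and 24 adjusted over the list alone, adjusted p = 0.0586), and ribosomal protein genes 13 of 362 and 14 (9 and 9, adjusted p = 0.0924). In all, the authors' deposited table holds 5359 genes higher and 4356 lower of 33492 in ZDB160 under arsenate.

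For ZDB160 given arsenate with phosphate, the authors' deposited table gives 5349 genes higher and 4906 lower of 33165 against the control, or 5830 in all with a log2 fold change of at least 1 in size. The glutathione S-transferase HORVU3Hr1G095620 rose by 8.37 in the authors' deposited table (adjusted p = 3.3e-57), and the phosphate transporter HORVU4Hr1G083550 fell from a signal of 7500 to 47.85 (−7.29, adjusted p = 6.66e-118). A peptide transporter fell by 7.00 on the log2 scale in the authors' deposited table (HORVU2Hr1G007730), and a quinone dehydrogenase that guards against oxidation rose by 7.92 (HORVU5Hr1G094820). Glutathione S-transferases had 47 of 106 higher and 8 lower in the authors' deposited table (48 and 8 adjusted over the list alone, cameraPR adjusted p = 6.32e-14), and aquaporins 1 of 43 and 25 (1 and 27, adjusted p = 7.44e-19). Peroxidases had 30 of 302 higher and 141 lower in the authors' deposited table (30 and 146 adjusted over the list alone, adjusted p = 1.61e-09), and expansins and cell wall genes 19 of 296 and 92 (19 and 99, adjusted p = 0.000481). Heat shock genes had 76 of 243 higher and 34 lower in the authors' deposited table (81 and 38 adjusted over the list alone, adjusted p = 0.00282), sulfate genes 15 of 46 and 3 (16 and 4, adjusted p = 0.0115), and iron and zinc genes 9 of 99 and 15 (9 and 15, adjusted p = 0.504).

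Of 7740 genes that the authors' deposited tables call in both treatments of ZDB160, 6407 (82.8%) changed less with phosphate, with median sizes of 1.34 against 1.7 on the log2 scale. In the authors' deposited tables for ZDB475 this held for 5884 of 6474 (90.9%). Fold changes from the libraries and from the authors' deposited tables correlated across genes at 0.986 for ZDB475 under arsenate and 0.959 with phosphate as well.

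The genotypes moved many of the same genes in the authors' deposited tables. Under arsenate 3721 genes were higher and 2114 lower in both genotypes, against 996.2 and 482.6 if calls in the authors' deposited tables were independent, and 64 went opposite ways. Their log2 fold changes correlated at 0.738 across genes in the authors' deposited tables, and at 0.737 for arsenate with phosphate. The response itself differed for 551 of 31574 genes under arsenate and for 682 of 31192 with phosphate as well, by the approximate test on the authors' deposited tables, and for 279 and 219 with the ZDB475 arm taken from the libraries without the pair that stood apart. Genes of mugineic acid synthesis were among those that differed. IDS3 (HORVU4Hr1G081520, 3 reads in all in the ZDB475 arsenate libraries) fell by −2.25 in ZDB160 in the authors' deposited table (adjusted p = 0.0199) and further in ZDB475 (adjusted p = 9.36e-06 for the difference in the authors' deposited tables). A nicotianamine synthase (HORVU4Hr1G053850) did not pass in ZDB160 (−1.15, adjusted p = 0.389) and had −9.16 in ZDB475 in the authors' deposited tables (adjusted p = 2.18e-05 for the difference).

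**Figure D3:**
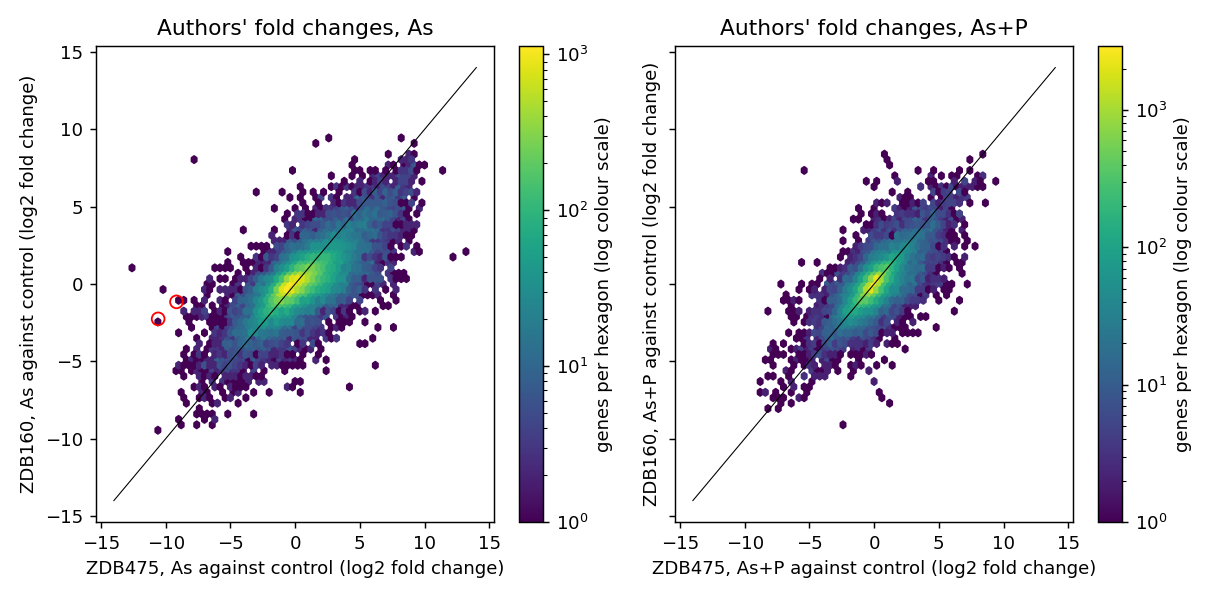
Log2 fold changes against control in ZDB475 and ZDB160 from the authors' deposited tables, under arsenate and under arsenate with phosphate. Shading counts genes, the line marks equality, and red circles mark HORVU4Hr1G081520 and HORVU4Hr1G053850, which lie far below 0 in ZDB475 under arsenate.

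Phosphate under arsenate was compared in ZDB160 as well, where lists passed only by camera with the preset correlation and not by fry. Ribosomal protein genes stood higher with phosphate by a median of 0.25 (camera adjusted p = 7.06e-07, adjusted p = 0.814 with an estimated correlation). Aquaporins stood higher by 0.46 (adjusted p = 0.000108, adjusted p = 0.65 with an estimated correlation), peroxidases by 0.14 (adjusted p = 9.98e-05, adjusted p = 0.65 with an estimated correlation), and expansins and cell wall genes by 0.07 (adjusted p = 0.00548, adjusted p = 0.65 with an estimated correlation). Iron and zinc genes stood higher by 0.29 (adjusted p = 0.00177, adjusted p = 0.65 with an estimated correlation, 0.11 without arsenate replicate 3 and 0.248 without both libraries that stood apart). Abscisic acid, LEA and dehydrin genes stood lower by −0.50 (adjusted p = 0.000167, adjusted p = 0.65 with an estimated correlation). A dehydrin, a protein of water stress, fell within that list (HORVU3Hr1G089300, −4.21 ± 0.85 SE, n = 3, adjusted p = 0.0107 over the list alone and 0.434 over all genes). Jasmonate genes stood lower by −0.28 (adjusted p = 0.00896, adjusted p = 0.814 with an estimated correlation).

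With edgeR, 1 gene rose and 1 fell with phosphate in ZDB160, and 1556 had an unadjusted p under 0.05. Neither has a description, and both were chosen after their values were seen. HORVU6Hr1G065760 fell from 6.4 ± 3.67 to 0.164 ± 0.107 CPM (−5.23 ± 0.609, n = 3, adjusted p = 0.0171), and HORVU7Hr1G010690 rose from 0.3 ± 0.157 to 3.38 ± 0.479 CPM (3.46 ± 0.409, n = 3, adjusted p = 0.0171). The count of 2 was 182 with DESeq2, 9137 with a quality weight per library, 4202 without both libraries that stood apart, 1 with total counts as the only scaling, and 0 with only the groups compared. It was 0 without arsenate replicate 1 or 2 or without replicate 1 or 2 given both, 19 without arsenate replicate 3, and 4 and 6 without ZDB475 arsenate replicate 1 and ZDB475 replicate 1 given both.

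The genotypes were then compared under arsenate, without a control level for ZDB160 in this comparison. The glutathione S-transferase F4 was higher in ZDB160, at 255 ± 90.5 against 9.84 ± 4.98 CPM (HORVU5Hr1G006330, 4.71 ± 0.519 SE, n = 3, adjusted p = 6.17e-05). The metallothionein HORVU1Hr1G059580 was higher as well, at 110 ± 76.5 against 6.95 ± 2.85 CPM (4.0 ± 0.84, n = 3, adjusted p = 0.00545). The glycerophosphodiester phosphodiesterase HORVU2Hr1G070700 was lower in ZDB160, at 191 ± 82.1 against 1496 ± 804 CPM (−2.97 ± 0.493, n = 3, adjusted p = 0.0012, and 0.0753 with only the groups compared). IDS3 stood at 106 ± 30.7 CPM in ZDB160 and at 3 reads in all in ZDB475 (HORVU4Hr1G081520). Phytochelatin synthase was lower in ZDB160 (HORVU7Hr1G040110, −3.86 ± 0.956, n = 3, adjusted p = 0.013), and by −0.86 without ZDB475 arsenate replicate 1. Its adjusted p was 0.0517 without ZDB160 arsenate replicate 2, 0.0867 with quality weights, 0.158 with only the groups compared and 0.057 with limma on log2 FPKM.

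Several genes had reads in a single genotype under arsenate. A cytochrome P450 described as a coumaroyl shikimate hydroxylase of lignin synthesis had 60.2 ± 9.74 CPM in ZDB160 and 0 reads in ZDB475, at least 1070-fold higher (HORVU0Hr1G031710, adjusted p = 6.89e-06). An origin recognition complex gene of DNA replication was at least 933-fold higher (BGI_novel_G003028) and the disease resistance gene RPM1 at least 556-fold higher (HORVU3Hr1G004100). A jacalin-type lectin had 0 reads in ZDB160 and 125 ± 44.9 CPM in ZDB475, at least 3130-fold lower (BGI_novel_G000077). The same genes stood apart under arsenate with phosphate, at least 1590-fold higher for HORVU0Hr1G031710, at least 1310-fold higher for BGI_novel_G003028 and at least 3560-fold lower for BGI_novel_G000077. Whether a genotype without reads lacks the gene, or has a sequence that the reference does not match, was not tested. These folds may therefore not reflect expression. A partial mismatch could also act on genes with reads in both genotypes. Other differences in level between the genotypes, here and under arsenate with phosphate, carry the same limit.

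No list passed as a whole between genotypes under arsenate. Iron and zinc genes had 23 of 85 higher and 10 lower in ZDB160 (23 and 10 adjusted over the list alone), pathogenesis-related proteins and chitinases 2 of 134 and 30 (2 and 30), and jasmonate genes 0 of 55 and 13 (1 and 13), each with a camera adjusted p of 0.0501. The nicotianamine synthase HORVU4Hr1G053850 was higher in ZDB160, at 270.1 ± 80.3 against 0.62 ± 0.351 CPM (8.80 ± 1.51, adjusted p = 0.00149, and 0.409 with quality weights). A chitinase, which breaks down fungal walls, was lower at 30.8 ± 2.99 against 188 ± 88 CPM (HORVU3Hr1G084220, −2.61 ± 0.405, adjusted p = 0.000766). Heat shock genes had 14 of 211 higher and 52 lower (camera adjusted p = 0.134). Without ZDB160 arsenate replicate 3, 4 lists passed.

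In all, 2379 genes were higher and 3892 lower in ZDB160 than in ZDB475 under arsenate. The count of 6271 was 4111 with total counts as the only scaling, 1271 with only the groups compared, and 4057 and 3796 without ZDB160 arsenate replicates 1 and 2, and 7839 without both libraries that stood apart. The share on the higher side was 37.9%, against 52.1% with total counts, which moved the median of all genes to 0.38, and 61.4% with limma on log2 FPKM.

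Under arsenate with phosphate, histone genes differed between the genotypes as a list by camera, with an adjusted p of 0.000816, and did not with an estimated correlation (0.916) or by fry (0.0904). Histone H4 stood at 6.95 ± 0.876 CPM in ZDB160 and 73.3 ± 5.02 CPM in ZDB475 (HORVU6Hr1G011780, −3.40 ± 0.385 SE, n = 3, adjusted p = 7.04e-05), while the centromeric histone H3 was higher in ZDB160 (HORVU1Hr1G068770, 3.96 ± 0.307, n = 3, adjusted p = 4.07e-06). Of 230 histone and replication genes, 16 were higher, 59 lower and 155 did not pass (17 and 94 adjusted over the list alone, camera adjusted p = 0.000816). Ribosomal protein genes had 9 of 317 higher, 32 lower and 276 not passing (9 and 30 adjusted over the list alone, adjusted p = 0.0209, adjusted p = 0.916 with an estimated correlation), with the L14e gene HORVU2Hr1G089090 lower (−6.63 ± 0.678) and the L37e gene BGI_novel_G001766 higher (3.80 ± 0.385).

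Iron and zinc genes had 18 of 85 higher, 3 lower and 64 not passing in ZDB160 under arsenate with phosphate (21 and 4 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.916 with an estimated correlation). A methylthioribose-1-phosphate isomerase of the methionine cycle, which feeds mugineic acid synthesis, stood at 687 ± 312 against 107 ± 3.87 CPM (HORVU4Hr1G016410, 2.69 ± 0.568, adjusted p = 0.00664). That list had an adjusted p of 0.184 without ZDB475 arsenate replicate 1, 0.0532 without ZDB160 arsenate replicate 3 and 0.201 without both. ABC transporters had 8 of 65 higher, 3 lower and 54 not passing (9 and 3 adjusted over the list alone, adjusted p = 0.046, adjusted p = 0.916 with an estimated correlation, 0.0758 without ZDB475 arsenate replicate 1 and 0.0544 without both), with ABCB4 higher (HORVU3Hr1G084670, 2.17 ± 0.478). The glutathione S-transferase F4 stood at 241 ± 34.8 against 36.8 ± 13.5 CPM (HORVU5Hr1G006330, 2.71 ± 0.472, adjusted p = 0.00181). In all, 1542 genes were higher and 2104 lower in ZDB160 under arsenate with phosphate. The count of 3646 was 5592 with DESeq2, 11591 with a quality weight per library, 9239 with only the groups compared and 9653 without both libraries that stood apart. It was 7057 without ZDB475 arsenate replicate 1, 2331 and 2166 without ZDB160 replicates 2 and 3 given both, and 2325 without ZDB475 replicate 3 given both.

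Between the treatments, 1197 genes were higher in ZDB160 under both and 1634 lower under both, against 135.4 and 302.2 if the calls were independent, and these comparisons share no library. A sequence that the reference matches less well in one genotype would recur under both treatments, so this overlap does not separate it from expression.

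The effect of phosphate was last compared between genotypes, where lists passed only by camera with the preset correlation and not by fry. Ribosomal protein genes gained less with phosphate in ZDB160 than in ZDB475, by a median difference of −0.59 (camera adjusted p = 3.12e-09, adjusted p = 0.983 with an estimated correlation). Histone genes differed by −0.44 (adjusted p = 0.000275, adjusted p = 0.983 with an estimated correlation) and jasmonate genes by 0.66 (adjusted p = 0.00816, adjusted p = 0.983 with an estimated correlation). Without ZDB160 arsenate replicate 3 these adjusted p were 0.24, 0.993 and 0.24, jasmonate genes had 0.95 without ZDB475 arsenate replicate 1, and without both libraries all 3 lists changed direction, with 0.501, 0.727 and 0.253. With edgeR 0 genes passed, with a smallest adjusted p of 0.577 and 1358 at an unadjusted p under 0.05. DESeq2 called 24, limma on log2 FPKM 1 and limma voom with quality weights 1, and edgeR called 5 without ZDB475 arsenate replicate 3 and 1 without ZDB160 arsenate replicate 3. The aquaporin PIP2-2 was among the 10 genes with the smallest p (HORVU5Hr1G027240, 3.12 ± 0.729 SE, n = 3, adjusted p = 0.81).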

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

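The tests of a few genes taking the counts, of a swap of libraries, of the mugineic acid genes and of the difference between genotypes were chosen after the results were seen.

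The response to treatment differed between the genotypes, which is why the following results are given here. By the approximate test on the authors' deposited tables, the change under arsenate differed for 551 genes, 145 higher and 406 lower in ZDB160, and the change under arsenate with phosphate for 682, 292 higher and 390 lower. With the ZDB475 arm taken from the libraries without the pair that stood apart, these counts were 279, 119 higher and 160 lower, and 219, 123 higher and 96 lower, so the balance under arsenate with phosphate turned. Iron and zinc uptake differed as a list under arsenate (adjusted p = 2.11e-06, medians in the authors' deposited tables of −0.53 in ZDB160 and −1.03 in ZDB475) and under arsenate with phosphate (adjusted p = 0.000623), and with that other arm the values were 0.00182 and 0.000203. Abscisic acid, LEA and dehydrin genes differed under arsenate (adjusted p = 0.000492, and 0.0203 with the other arm), as did ribosomal protein genes (0.000198, and 0.0203). Heat shock genes (0.0342) and jasmonate genes (0.0454) differed under arsenate, and with the other arm did not (0.624 and 0.981). With the other arm alone, histone genes and the photosynthesis marker list differed under arsenate (0.0203 each), and abscisic acid, LEA and dehydrin genes with phosphate as well (0.0449). Glutathione, phytochelatin and metallothionein genes differed under arsenate with phosphate (0.00665, and 0.0752 with the other arm). These list values rest on the preset correlation and were not repeated with an estimated one. With an estimated correlation the list results from the libraries ended.

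Single genes differed as well in the authors' deposited tables, with values for ZDB160 first and adjusted p of the difference. IDS3 (HORVU4Hr1G081520) had an adjusted p of 9.36e-06 and the nicotianamine synthase HORVU4Hr1G053850 of 2.18e-05 under arsenate. The helicase gene BGI_novel_G002491 had log2 fold changes of −3.65 in ZDB160 and 5.91 in ZDB475 in the authors' deposited tables (adjusted p = 3.86e-10). A peroxisomal enzyme of fatty acid breakdown had −1.35 and 6.92 under arsenate (HORVU7Hr1G027830, adjusted p = 5.51e-10) and −2.87 and 4.70 with phosphate as well (2.07e-12) in the authors' deposited tables. Under arsenate with phosphate the cytochrome P450 HORVU7Hr1G031730 had 4.40 and 1.84 (1.22e-10), the calcium-dependent kinase HORVU4Hr1G004540 1.78 and −0.50 (1.52e-09), and the protein phosphatase 2C HORVU3Hr1G059170 −3.01 and 2.89 (9.38e-13) in the authors' deposited tables.

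The effect of phosphate under arsenate differed between the genotypes for ribosomal protein genes (camera adjusted p = 3.12e-09), histone genes (0.000275) and jasmonate genes (0.00816), each with an adjusted p of 0.983 with an estimated correlation. These differences rest on the pair of libraries that stood apart, since without both the adjusted p were 0.501, 0.727 and 0.253 and the directions changed. For single genes edgeR called 0, a count that 40 of 40 splits of the libraries reach whatever the data (4 in the highest of the others), so these splits say nothing about chance.

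Replicate 1 of ZDB475 under arsenate stood apart from its replicates. The tables argue against a library of the other genotype. Of 143 genes with 20 or more counts in every ZDB160 library and at most 2 in all over the other ZDB475 libraries, 8.39% had 3 or more counts in it. They argue against gene length, with a Spearman correlation of 0.023 with the ratio to its replicates across genes. Without its 100 most abundant genes its highest correlation with a replicate was 0.838, against at least 0.931 within the groups not given arsenate alone. The difference was therefore not confined to those genes. Whether a few genes taking the counts caused it is not decided, since leaving out 100 genes hardly moves a correlation over the 26998 others and does not restore their depth. A stronger response to arsenate stays open, since its score over genes that the authors' deposited table calls in ZDB160 was 5.16, against 3.88 and 3.72 in its replicates. The score is the mean log2 difference from the ZDB475 controls over the higher genes, minus that over the lower genes. Damage to the tissue or to the RNA, which could raise the same genes, was not tested.

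Replicate 3 of ZDB160 under arsenate lay near the libraries given phosphate as well. A swap with one of them is argued against, since 0 of those 3 libraries lay nearer to the other arsenate libraries than to each other. A weaker response to arsenate stays open, with a score of 2.71 against 3.98 and 3.85 in its replicates. These scores, over genes called in ZDB475, are also taken against the ZDB475 controls and so include differences between genotypes. A single library given phosphate under a wrong label stays open too. The score of replicate 3, 2.71, exceeded the lowest of the libraries given phosphate as well, 2.5, by 0.21. It also lay above their highest, 2.63, and so outside their range, though nearer to it than to the scores of its replicates. Nothing in the tables decides between these.

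Nicotianamine synthase and mugineic acid genes fell in ZDB475 under arsenate, with 17 of the 24 tested genes of these descriptions lower, 1 higher and 6 not passing. Summed over the 24, whatever their control level, they had 9100, 38400 and 1950 CPM in control replicates 1 to 3 and 768, 260 and 268 CPM under arsenate, and much of the arsenate sum came from a gene described as an ACC oxidase that rose to 439, 110 and 77.7 CPM (HORVU7Hr1G060070). Over the 24 genes the lowest control was 2.54 times the highest arsenate library, a ratio lowered by the ACC oxidase gene, the 1 that rose. Over the 17 with a mean of at least 50 CPM in the controls, the lowest control had 1890 CPM and the highest arsenate library 325 CPM. In both sums every control library lay above every arsenate library. The ratio over the 24 genes does not decide whether high levels in some controls are the whole cause. The 17 were picked by their control level, which favours a high ratio, so their sums do not decide it either. A part in the size of the fall stays open too, since the controls ran from 1890 to 38300 CPM over the 17. A reference that the wild genotype does not match is argued against, since it would act alike on the control and arsenate libraries of ZDB475, while the median log2 fold change of the 24 genes was −7.43 (quartiles −9.12 and −2.68).

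For the other comparisons the splits of 6 libraries number 10, too few for a share under 0.05. In ZDB475 the real split gave 11267 genes under arsenate and 3931 with phosphate as well, the highest other split 0 in each, and 1 of the 10 splits gave as many. Between arsenate with phosphate and arsenate, the real split gave 0 in ZDB475 with 49 in the highest other, a count of 0 that 10 of 10 reach whatever the data, and 2 in ZDB160 with 1 in the highest other. The split with 49 exchanged replicate 3 of the groups. Whether its calls reflect chance or a structure of the samples cannot be told from 10 splits. Between genotypes the real split gave 6271 under arsenate with 1054 in the highest other, and 3646 with phosphate as well with 1 in the highest other.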

How the results depend on the processing

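Total counts as the only scaling, quality weights per library and leaving out a pair of libraries were chosen after the data were seen.

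No named gene reversed, though these genes were picked from the same data for large or clear changes, which favours that result. With DESeq2, 812 of 836 named results kept their side of the threshold, with RLE factors 828, without a filter 804, with a replicate block 794, with total counts 747, with quality weights 774, and without both libraries that stood apart 809. With limma on log2 FPKM it was 711 of 792, and with only the groups compared 686 of 808.

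For arsenate with phosphate against arsenate, ZDB475 had 0 genes with edgeR (8324 at an unadjusted p under 0.05), 5520 with DESeq2, 90 with limma on log2 FPKM, 129 with quality weights and 2327 without both libraries. ZDB160 had 2, with DESeq2 182, with quality weights 9137, without both libraries 4202, with total counts 1, and with a replicate block or only the groups compared 0. The difference between genotypes had 0 with edgeR (1358 at an unadjusted p under 0.05), 24 with DESeq2, 1 each with limma on log2 FPKM and with quality weights, and 1 without both libraries.

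With only the groups compared, arsenate against control in ZDB475 had 5592 genes against 11267, arsenate with phosphate against control 9377 against 3931, and the genotypes 1271 against 6271 under arsenate and 9239 against 3646 with phosphate as well. Arsenate with phosphate against control had 12248 with quality weights and 9776 without both libraries. The genotypes under arsenate had 4111 with total counts. With phosphate as well they had 5592 with DESeq2, 11591 with quality weights and 9653 without both libraries. The authors' deposited table for ZDB160 given both had 5830 with a log2 fold change of at least 1, against 10255. The common coefficient of variation between replicates was 0.45, and 0.31 without both libraries, so the spread they add bears on these counts; for the other settings the cause was not tested.

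With each library left out in turn, the counts ran from 8085 to 12726 for ZDB475 under arsenate, 2169 to 7496 with phosphate as well, 0 to 7428 between these, 0 to 19 for phosphate in ZDB160, 3796 to 9186 and 2166 to 7057 between genotypes, and 0 to 5 for the difference between genotypes.

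Of 203 list results, 157 kept their side of the threshold with an estimated correlation, 167 with fry and 184 without both libraries. With an estimated correlation 0 lists passed in any of the 7 comparisons, against 13 and 11 with the preset one for the treatments of ZDB475, 8 and 7 for phosphate in ZDB475 and ZDB160, 0 and 4 between genotypes, and 3 for the difference of the phosphate effect. Fry, which tests the genes of a list without comparing them with others, passed 19 lists in ZDB475 under arsenate, among them MYB (0.015), NAC (0.00338) and ethylene genes (0.00598), which camera did not pass, and 18 given both. Between genotypes it passed 0 under arsenate and 3 with phosphate as well (ABC transporters, ethylene and auxin genes, 0.0432 each, but not histone, 0.0904, iron, 0.0904, or ribosomal protein genes, 0.266), and for phosphate in either genotype and its difference 0. Between genotypes under arsenate 3 lists passed without both libraries (0 to 4 with 1 of the 2 left out), under arsenate with phosphate 2 (2 to 4), and for the difference of the phosphate effect 1 (1 to 3). Reversed were ribosomal proteins between genotypes under arsenate without both libraries (0.000904), and for the difference of the phosphate effect jasmonate genes with 1 library left out (0.24 to 0.95, reversed without ZDB475 arsenate replicate 1), and without both libraries jasmonate (0.253), ribosomal protein (0.501) and histone genes (0.727).

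The labels state no pairing of samples by replicate number. Over 30 pairs of libraries with equal numbers, deviations from the group means correlated at −0.293 to 0.289, 5 of them over 0.1. With means of 3 libraries this check is weak and does not exclude a pairing. With the numbers as a block, ZDB475 had 10580 genes under arsenate and 3484 with phosphate as well. In simulated counts for arsenate against control in ZDB475, 4% of genes changed 2-fold were recovered, and 48% at 4-fold. Few genes were changed in these counts, so the adjusted threshold was stricter than in the real comparison, where many genes passed. These shares therefore do not give the power of that comparison.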

Other observations

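The D-hordein genes, the mugineic acid sums and their tests and the response scores without libraries were chosen after the results were seen.

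Transcripts of a grain storage protein rose in roots. The D-hordein gene HORVU1Hr1G064080 had 0.131, 0.135 and 2.12 CPM in the ZDB475 controls, 2420, 179 and 125 CPM under arsenate and 169, 18.2 and 66.6 CPM with phosphate as well. It rose under arsenate (log2 fold change 10.12 ± 1.9 SE, n = 3, edgeR adjusted p = 0.00133, and 7.48 without both libraries that stood apart) and with phosphate as well (6.70 ± 1.66, adjusted p = 0.0169). In ZDB160 it had 16.5, 15.7 and 1.48 CPM under arsenate and 0.285, 2.23 and 0.673 CPM with phosphate as well. A second seed storage gene, HORVU1Hr1G066650, rose under arsenate in ZDB475 (6.12 ± 1.03, adjusted p = 0.000686, and 3.84 without both libraries). With phosphate as well it did not pass (2.79 ± 0.89, edgeR adjusted p = 0.0531), and without both libraries it did (2.76, adjusted p = 0.0018). The third tested member of that list is a phosphatase subunit matched by its description and not a storage gene (HORVU5Hr1G043520). The other 12 members, B and C hordeins among them, had at most 14 counts in any library.

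The 17 nicotianamine synthase and mugineic acid genes with a mean of at least 50 CPM in the ZDB475 controls summed in ZDB475 to 9060, 38300 and 1890 CPM in control replicates 1 to 3, to 325, 137 and 150 CPM under arsenate and to 1740, 517 and 966 CPM with phosphate as well. In ZDB160 they summed to 2090, 4020 and 2460 CPM under arsenate and to 2470, 6570 and 11800 CPM with phosphate as well. The mean log2 sum was 9.90 with phosphate against 7.57 in ZDB475 and 12.49 against 11.42 in ZDB160 (exact two-sided permutation within genotype over 400 arrangements, p = 0.015). Genes of this family had been seen higher with phosphate in ZDB475 before they were picked, so this p decides nothing.

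Phosphate may weaken the whole response to arsenate. The response score, over genes that the other genotype's comparison calls, fell from 4.25 to 2.95 in ZDB475 and from 3.51 to 2.56 in ZDB160 (exact two-sided permutation within genotype over 400 arrangements, p = 0.005, the smallest they can give). Every score was taken against the ZDB475 controls. The ZDB160 scores thus include differences between genotypes, and their size cannot be set against that of the ZDB475 scores. Without both arsenate libraries that stood apart the arsenate scores were 3.80 and 3.92 (exact two-sided permutation within genotype over 100 arrangements, p = 0.01), and without the library of ZDB475 alone the exact permutation p was 0.015 over 200.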
